A study of Mus musculus with 4 samples.

How the data were processed

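Total RNA from the livers of male C57BL/6J mice, 4 samples with 2 per diet, was amplified, turned into biotin-labelled single-stranded cDNA and hybridised to Mouse Gene 2.1 ST array strips read on a GeneAtlas scanner, per the labels' protocols. These arrays carry oligonucleotides along the length of each transcript and give 1 summary value per transcript row. The deposited values come from Transcriptome Analysis Console, per the submitters' processing notes; its version, the summarization method, the background correction and the normalization are not given in the sources used here. The values were read as log2 signals made by the authors. The base of the logarithm is not stated, and log2 was inferred from the values, whose maximum of 12.1 lies above what the natural log of a 16-bit scanner reading can reach and which spread over the range usual for log2 summaries. All fold changes depend on that inference. The arrays share nearly the same median and maximum, genes are not centred, and each column is 1 array. Whether an array holds RNA of 1 animal or of several is not stated. The number of unused columns of per-sample values was 0.

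The table holds 34472 rows. The platform annotation named exactly 1 gene for 23521 rows, several genes for 1814 and none for 9137. Of the 23521 rows, 23328 were found in the RefSeq gene table of assembly GRCm38.p6, used for names alone, and it updated 0 symbols. Rows naming several genes or none stayed out of the tests. For the 1082 genes with more than 1 row, the row with the highest mean over all 4 arrays was used, which left 22180 genes. Rows of a gene can disagree: the dimmer rows of Cd24a, Mmp7 and Lpl differed by 0.27, 0.18 and 0.69 where the rows used rose by 3.12, 5.26 and 4.01. The deposited values were tested as they stand, with no further normalization, no pseudocount and no filter on dim genes, since neither background nor detection values were analysed here.

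Groups were taken from the sample titles. Genes were compared between MCD diet and normal diet livers with limma 3.58.1 in R 4.3.3 (linear model and empirical Bayes moderation, two-sided), using all 4 arrays without a block, with Benjamini-Hochberg adjustment over all genes tested and a threshold on adjusted p of 0.05. The 2 residual degrees of freedom per gene were raised to 6.06 by the moderation. A total of 52 gene lists with 999 genes (pathways, zonation, sex bias, liver cell types and tissues that a liver sample can carry) were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Of those genes 900 were measured and 99 were not analysed here. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01, with adjustment over the 52 lists. Camera with an estimated correlation and the rotation test fry served as alternatives. Counts of members adjusted over the list alone use limma's p-values adjusted within the list.

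The genes named were the 10 largest increases and the 10 largest decreases among called genes whose arrays do not overlap, leaving out predicted genes and members of families with near-identical copies unless called uncertain, up to 4 called members of each list with the largest differences (or up to 2 members as values where none was called), and always Scd1, Fgf21, Cyp7a1, Col1a1, Acta2, Plin2, Mat1a, Pemt, Bhmt, Trem2, Timp1, Tnf, Krt19, Mki67, Alb and Clec4f. A further 2 genes of that last set were not analysed here. Of the 174 genes that the rule allows, those whose call held under the alternatives were named by preference. Genes outside the rule, which are marked as such or appear in the closing observations, were chosen after their values were seen.

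The gene test was tested on 20 simulated data sets with 200 changed genes among 22180, drawn with the spread of these arrays. It recovered 47.8% of genes changed by 1 on the log2 scale and 96.2% of those changed by 2, and 5.36% of its calls were false. In the simulated list test, 20 of 20 lists shifted by 1 were called, and 1 of 972 unshifted lists. The simulated genes varied independently, so this does not show how often lists are falsely called where their genes are correlated. Differences of 2-fold were thus often missed in these simulations with 2 arrays per diet. The adjustment is stricter where few genes change, and 2214 genes were called in the data, so recovery there may differ. The alternatives, whose effect is given in the closing section, were quantile normalization of the 4 arrays, centring each array on its median, leaving out the dimmest 25% or 50% of genes, an intensity trend in the moderation, testing all rows, averaging the rows of a gene, an unadjusted p under 0.05 with at least 2-fold change, the replicate number as a block, and leaving out each array in turn. A test of one list within the members of another was added after the data were seen. Coordinates are not given, since the table was used by gene name.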

Results

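Messenger RNA levels were measured in the liver of male C57BL/6J mice, an inbred laboratory strain. From 6 weeks of age the mice received a normal diet or a methionine- and choline-deficient diet (MCD diet) for 20 weeks. Choline is needed to make phosphatidylcholine for the export of lipoproteins from the liver, and the MCD diet is a widely used way to produce fatty liver with inflammation in mice. Each diet was represented by 2 samples, each hybridised to its own gene-level array, for 4 arrays in all. The labels name the samples as mice with a number and do not say more about how they were taken, so the p-values measure the spread between these samples. The deposited log2 signals had medians of 2.63 and 2.65 on the normal diet arrays and 2.57 and 2.63 on the MCD diet arrays, and the brightest row on each array reached 12.1. Their number limits the precision, and no background or detection value was analysed here. Arrays of the same diet resembled each other more than arrays of different diets. Across genes, which are not independent replicates, the SD of the difference between arrays was 0.267 on the log2 scale for the normal diet pair and 0.274 for the MCD diet pair, against 0.528 to 0.598 between diets. The first principal component held 79.8% of the variance and separated the diets.

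The only comparison that the design gives asks which liver transcripts the MCD diet changes. In MCD diet livers, markers of lipid-associated macrophages, enzymes and inhibitors that remodel extracellular matrix and biliary markers were higher, while male-biased, lipid-synthesising, bile acid synthesis and complement genes were lower. These lists were called by camera at a preset correlation between genes, and 0 of the 52 lists tested were called with an estimated correlation (lowest adjusted p = 0.235). Gpnmb, a glycoprotein of macrophages with a high lysosomal load, rose by 7.33 ± 0.20 on the log2 scale (161-fold; ± is the standard error of the log2 difference throughout, n = 2 arrays per diet; limma adjusted p = 0.000163). The normal diet signal of Gpnmb was dim, at 2.40. Sult1e1, which encodes estrogen sulfotransferase, rose by 6.34 ± 0.19 (81.1-fold) from a dim normal diet signal of 1.97. The matrix metalloproteinases Mmp12 and Mmp7 rose by 5.59 ± 0.27 and 5.26 ± 0.24, from low normal diet signals of 2.87 and 2.98. Since signal over background was not analysed, the sizes and the order of rises from such signals are uncertain. The other 6 of the 10 largest increases were those of the lysosomal proton pump subunit Atp6v0d2 (4.64 ± 0.22), the fungal pattern receptor Clec7a (4.34 ± 0.14), the carbonic anhydrase Car2 (4.16 ± 0.17) and the actin bundler Pls1 (4.08 ± 0.24), followed by Ly6d (4.06 ± 0.13) and the asparagine synthetase Asns (4.05 ± 0.24). In the other direction Slco1a1, an organic anion transporter of hepatocytes, fell by 6.95 ± 0.13 (124-fold lower; limma adjusted p = 3.09e-05), to a dim MCD diet signal of 2.43. The fatty acid elongase Elovl3 fell by 5.37 ± 0.21 (41.4-fold lower) and the mannose-binding lectin Mbl2 fell by 4.53 ± 0.14 (23.1-fold lower). The oxysterol hydroxylase Cyp7b1 fell by 4.09 ± 0.18, Dpys by 3.98 ± 0.14, the complement component C6 by 3.81 ± 0.20, the stearoyl-CoA desaturase Scd1 by 3.81 ± 0.26, Keg1 by 3.77 ± 0.21, Cmah by 3.75 ± 0.21 and the sodium channel subunit Scnn1a by 3.57 ± 0.21. Not counted here are 3 further increases and 14 further decreases as large as these, of predicted genes or members of multigene families, whose probes may share signal with near-identical copies. Among them Serpina4-ps1 (fell by 7.42 ± 0.34) and Hsd3b5 (fell by 7.20 ± 0.13) fell further than Slco1a1, both uncertain for that reason. Hsd3b5, like Slco1a1, ended at a dim signal (1.48 in MCD diet livers), so the order of their falls is uncertain too. Alb, the albumin gene, differed by -0.04 ± 0.12 at a level near the top of the scale.

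In all, 2214 of 22180 genes (9.98%) changed at an adjusted p under 0.05 in limma, 1412 of them higher and 802 lower in MCD diet livers. Of these, 1071 changed at least 2-fold, 725 higher and 346 lower. The smallest difference called was 0.50 on the log2 scale. Calls were scarce among dim genes, at 0.234% of the 25% of genes with the lowest mean signal against 18.0% of the 25% with the highest. The arrays of the diets did not overlap for 54.2% of the genes, where chance alone gives 33.3%. The count rests on the number of arrays. It was 1321 without normal diet replicate 1, 1093 without normal diet replicate 2 and 1050 without MCD diet replicate 1. It was 1493 without MCD diet replicate 2, where the lower genes numbered 482.

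**Figure D1:**
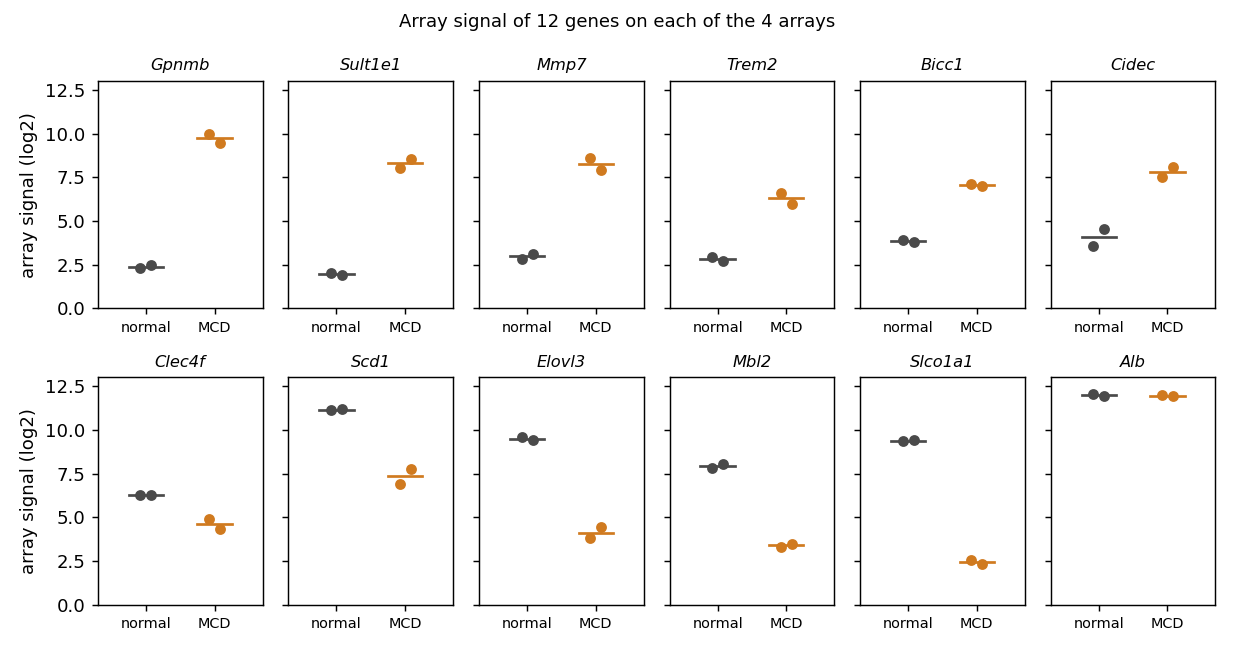
Array signal on the log2 scale (vertical axes) of 12 genes in the normal diet and MCD diet groups; each point is 1 array, and the horizontal lines are the means of the 2 arrays of a diet. The MCD diet arrays lie above the normal diet arrays for Gpnmb, Sult1e1, Mmp7, Trem2, Bicc1 and Cidec and below them for Clec4f, Scd1, Elovl3, Mbl2 and Slco1a1, while Alb differed by -0.04.

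Genes that differ between the sexes in mouse liver changed in these male mice, the male-biased ones downward and most of the called female-biased ones upward. Of 24 measured male-biased genes 20 fell and 0 rose (22 fell when adjusted over the list alone), with a median log2 difference of -2.61 and a camera adjusted p of 5.29e-26 (adjusted p = 0.235 with an estimated correlation). They included Slco1a1 and Elovl3, as well as Hsd3b5, a steroid dehydrogenase, and Selenbp2 (fell by 5.38 ± 0.32), both with close family members. Of 26 female-biased genes 14 rose and 2 fell (15 and 2 adjusted over the list alone). Their median was 1.34, and the camera adjusted p was 6.16e-09 (adjusted p = 0.345 with an estimated correlation). Sult1e1 headed this list, followed by Cyp2b9 (5.02 ± 0.38), Atp6v0d2, which is also on the macrophage and lysosome lists, and Cyp3a44 (4.12 ± 0.38). The signals of both cytochromes P450 may include near-identical copies. Other lists hold 6 of the male-biased and 4 of the female-biased genes. Within the genes of these lists alone, a test added after the data were seen set the male-biased below the female-biased genes (camera adjusted p = 6.97e-12, adjusted p = 0.0607 with an estimated correlation).

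Markers of monocyte-derived and lipid-associated macrophages rose almost as a block, whereas those of resident Kupffer cells went both ways. Of the 20 measured markers of the former 18 rose and 0 fell (19 adjusted over the list alone). The median of the list was 2.47 (camera adjusted p = 1.03e-22, adjusted p = 0.257 with an estimated correlation). Beside Gpnmb, Mmp12, Atp6v0d2 and Clec7a, the list holds the lipid receptor Trem2, which rose by 3.47 ± 0.22 (11.1-fold) from a dim normal diet signal of 2.83. Normal diet livers expressed 10 of the 20 above the median signal of all genes, and other lists hold 6 of them. Among 18 Kupffer cell markers 2 rose and 5 fell, the same numbers as adjusted over the list alone, with a median of -0.13, and the list was not called (camera adjusted p = 0.156, adjusted p = 0.387 with an estimated correlation). The rotation test fry, in contrast, called this list lower (fry adjusted p = 0.0274). The scavenger receptor Cd163 fell by 2.06 ± 0.13, the C-type lectin Clec4f by 1.66 ± 0.19 and the ficolin Fcna by 1.20 ± 0.14, and C6 fell as well but is also expressed by hepatocytes. Other lists hold 4 of the Kupffer cell markers, and 17 lay above the median signal in normal diet livers. Lysosomal genes rose with the macrophage markers. Of 23 measured, 16 rose and 0 fell (18 and 1 adjusted over the list alone). At a median of 0.76, the list had a camera adjusted p of 6.89e-12 (adjusted p = 0.372 with an estimated correlation). Among them were Cd68 (3.43 ± 0.24) and the cathepsin Ctss (3.07 ± 0.12). The list shares 3 members with others.

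Other immune markers moved less. Of 17 neutrophil markers 2 rose, as many as adjusted over the list alone, and the list was called higher with a median of 0.29 (camera adjusted p = 0.00275, adjusted p = 0.378 with an estimated correlation). Of the 17, 0 lay above the median signal in normal diet livers, and the lectin receptor Clec4d rose by 1.60 ± 0.20. Of 15 dendritic cell markers 2 rose (4 adjusted over the list alone), among them the transcription factor Irf8 (0.997 ± 0.12, a call lost with the mean of a gene's rows), with a median of 0.20 and a camera adjusted p of 0.0377 (adjusted p = 0.378 with an estimated correlation). The call was lost under quantile normalization, without the dimmest 50% of genes, and without normal diet replicate 1 or MCD diet replicate 2. T and NK cell markers gave 1 higher and 0 lower of 22, also adjusted over the list alone, the chemokine Ccl5 (0.80 ± 0.12). The list had a median of 0.05 and was not called (camera adjusted p = 0.295, adjusted p = 0.669 with an estimated correlation). The call of Ccl5 was lost without either normal diet array or MCD diet replicate 1. Of 15 markers of B cells and plasma cells 2 rose (2 higher and 1 lower adjusted over the list alone), including the immunoglobulin heavy chain gene Ighm (1.83 ± 0.17), and the list was not called (camera adjusted p = 0.984, adjusted p = 1 with an estimated correlation). Its median was -0.08 and its mean 0.13, so these differ in sign. The rise of Ighm is uncertain, since the gene belongs to a family with close copies and its rows disagree, the others differing by 0.18 to 2.13. Normal diet livers expressed 6 of the dendritic, 5 of the T and NK and 3 of the B and plasma cell markers above the median signal. Of 30 chemokine and cytokine genes 8 rose and 4 fell (8 and 5 adjusted over the list alone). Their median was 0.18, without a call (camera adjusted p = 0.114, adjusted p = 0.377 with an estimated correlation). Ccl3 rose by 2.96 ± 0.15 and Ccl9 fell by 1.45 ± 0.13, while Tnf differed by 0.22 ± 0.12 at a low signal (limma adjusted p = 0.344). Outside the naming rule, the cytokine genes Il18 and Il1b fell by 1.07 ± 0.17 and 0.70 ± 0.15. Interferon-stimulated genes gave 1 higher and 3 lower of 20 (3 and 7 adjusted over the list alone), with a median of -0.09 and no call (camera adjusted p = 0.35, adjusted p = 0.757 with an estimated correlation). Bst2 fell by 1.43 ± 0.13.

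Transcripts of extracellular matrix and of the enzymes that remodel it rose. Of 19 matrix genes of fibrosis 9 rose and 1 fell (10 and 1 adjusted over the list alone). Their median was 0.70, and the camera adjusted p was 1.32e-06 (adjusted p = 0.288 with an estimated correlation). The proteoglycan Lum rose by 2.91 ± 0.17, Thbs2 by 1.80 ± 0.19 and Col6a3 by 1.39 ± 0.13, and 17 of the 19 lay above the median signal in normal diet livers. The main fibrillar collagen gene Col1a1 rose by 0.98 ± 0.20 (limma adjusted p = 0.0327). Of 17 remodelling enzymes and inhibitors 9 rose and 0 fell, also adjusted over the list alone. The median of the list was 0.94 (camera adjusted p = 7.7e-09, adjusted p = 0.235 with an estimated correlation). Plat and Mmp2 rose by 2.40 ± 0.18 and 2.36 ± 0.21. Timp1, an inhibitor of metalloproteinases, differed by 0.34 ± 0.14 at a low signal and did not pass (limma adjusted p = 0.191). Markers of myofibroblasts and portal fibroblasts rose in 6 of 20 and fell in 0 (7 and 2 adjusted over the list alone). At a median of 0.55, the list had a camera adjusted p of 6.77e-05 (adjusted p = 0.373 with an estimated correlation). The growth factor receptors Pdgfra and Pdgfrb rose by 2.74 ± 0.12 and 1.38 ± 0.12, and Acta2, which encodes smooth muscle actin, rose by 1.35 ± 0.31 (limma adjusted p = 0.0495). The calls of Col1a1 and Acta2 were lost under quantile normalization and without either normal diet array or MCD diet replicate 2, and that of Acta2 also under median centring, with all rows tested and with a replicate block. Hepatic stellate cell markers, which rose in 3 and fell in 2 of 16 (7 and 4 adjusted over the list alone), were not called (median 0.43, camera adjusted p = 0.196, adjusted p = 0.669 with an estimated correlation). The hepatocyte growth factor gene Hgf rose by 1.53 ± 0.16 and Dcn by 1.39 ± 0.14, whereas Colec10 fell by 2.21 ± 0.22. Other lists hold 2 of the matrix genes, 3 of the remodelling genes and 5 of the myofibroblast markers. Normal diet livers expressed 9 of the myofibroblast and 15 of the stellate cell markers above the median signal.

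Biliary and oncofetal transcripts, which are low in adult hepatocytes, also rose. Of 20 measured markers of cholangiocytes and the ductular reaction 15 rose and 0 fell (17 adjusted over the list alone), with a median of 1.56 and a camera adjusted p of 7.34e-13 (adjusted p = 0.257 with an estimated correlation). The RNA-binding protein gene Bicc1 rose by 3.20 ± 0.12, Cd24a by 3.12 ± 0.27 and the epithelial adhesion molecule Epcam by 2.35 ± 0.19. The keratin Krt19 rose by 0.78 ± 0.14 (limma adjusted p = 0.0213) from a signal near the floor, a call that was lost without normal diet replicate 1 or either MCD diet array. Of 17 oncofetal and tumour-associated genes 12 rose and 0 fell (14 adjusted over the list alone). Their median was 1.60, and the camera adjusted p was 5.5e-12 (adjusted p = 0.235 with an estimated correlation). It was led by Ly6d, the lipocalin Lcn2 (3.91 ± 0.22, 15.0-fold) and the tetraspanin Tspan8 (3.45 ± 0.19). Each of these lists shares 4 members with others, and 8 of the biliary and 7 of the oncofetal genes lay above the median signal in normal diet livers. Cell cycle genes rose in 9 of 25 and fell in 0 (10 adjusted over the list alone). With a median of 0.31, the list was called higher (camera adjusted p = 2.56e-05, adjusted p = 0.257 with an estimated correlation). The cyclin Ccnd1 rose by 2.70 ± 0.13 (6.51-fold), the proliferation marker Mki67 by 1.33 ± 0.14 and the helicase subunit Mcm6 by 1.08 ± 0.14. Of 20 p53 target and senescence genes 4 rose and 0 fell (6 adjusted over the list alone). At a median of 0.09, the list had a camera adjusted p of 0.0384 (adjusted p = 0.573 with an estimated correlation). That call was lost under quantile normalization, without the dimmest 50% of genes, and without normal diet replicate 1 or MCD diet replicate 1, while Gadd45b rose by 3.11 ± 0.30. Genes of cell death and the inflammasome rose in 5 and fell in 1 of 17 (9 and 3 adjusted over the list alone), with a median of 0.40 and a camera adjusted p of 0.00369 (adjusted p = 0.288 with an estimated correlation), and the call was lost without the dimmest 50% of genes. Casp1, the caspase of the inflammasome, rose by 2.09 ± 0.20 and Mlkl, the effector of necroptosis, by 1.85 ± 0.14. Outside the naming rule, Gsdmd was the member that fell (by 0.88 ± 0.12), and Nlrp3, Pycard and Ripk3 did not pass the threshold.

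Lipid-synthesising genes fell while genes of lipid uptake rose. Of 18 genes of de novo lipogenesis 8 fell and 0 rose (12 adjusted over the list alone). The median was -0.99, and the camera adjusted p was 3e-07 (adjusted p = 0.288 with an estimated correlation). Beside Scd1, the lipogenic regulator Thrsp fell by 2.92 ± 0.16 and the acetyl-CoA carboxylase Acacb by 2.31 ± 0.15, and 17 of the 18 lay above the median signal in normal diet livers. Lipid uptake genes rose in 5 and fell in 1 of 11 (6 and 1 adjusted over the list alone). The median of the list was 0.91 (camera adjusted p = 0.0159, adjusted p = 0.377 with an estimated correlation). Lipoprotein lipase, Lpl, rose by 4.01 ± 0.29 (16.1-fold), the fatty acid translocase Cd36 by 3.19 ± 0.33 and Fabp5 by 2.42 ± 0.19. Other lists hold 6 of the 11, Lpl and Fabp5 also being macrophage markers here, and the call was lost without the dimmest 50% of genes. Of 15 lipid droplet genes 3 rose and 0 fell (4 adjusted over the list alone). The list had a median of 0.22 and was not called (camera adjusted p = 0.053, adjusted p = 0.541 with an estimated correlation). It was called higher under median centring. Cidec, which promotes growth of lipid droplets, rose by 3.75 ± 0.35 (13.4-fold), and the droplet coat gene Plin2 rose by 0.83 ± 0.16 (limma adjusted p = 0.0294), a call that was lost without any 1 of the 4 arrays. Cholesterol synthesis and uptake genes fell in 2 and rose in 0 of 19, also adjusted over the list alone. At a median of -0.41, the list had a camera adjusted p of 0.0495 (adjusted p = 0.735 with an estimated correlation). The sterol enzymes Tm7sf2 and Ebp fell by 1.93 ± 0.20 and 1.43 ± 0.14. The list's call was lost under quantile normalization, median centring and a replicate block, and without MCD diet replicate 1, and the median turned to 0.27 without normal diet replicate 1. Fatty acid oxidation and PPARalpha target genes gave 4 higher and 2 lower of 24 (4 and 4 adjusted over the list alone). Their median was 0.09, without a call (camera adjusted p = 0.958, adjusted p = 1 with an estimated correlation). Pdk4 rose by 3.02 ± 0.20 and the fatty acid carrier Fabp1 fell by 1.75 ± 0.21, and the rise of Acot2 (3.57 ± 0.27) may include signal of close copies. Apolipoprotein and VLDL assembly genes gave 1 higher and 2 lower of 15 (2 and 6 adjusted over the list alone), with a median of -0.22 and no call (camera adjusted p = 0.132, adjusted p = 0.378 with an estimated correlation). Apoa4 rose by 2.33 ± 0.22.

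The MCD diet lacks methionine and choline. Genes listed here for sulfur amino acid and methyl group metabolism fell as a list. What else differed between the diets was not analysed here, so the fall is not assigned to these nutrients. Of 20 genes of the methionine cycle and transsulfuration 9 fell and 0 rose (11 lower and 1 higher adjusted over the list alone), with a median of -0.65 and a camera adjusted p of 3.06e-05 (adjusted p = 0.257 with an estimated correlation). Aldh7a1, which can oxidise betaine aldehyde to betaine, fell by 1.56 ± 0.14, the nicotinamide methyltransferase Nnmt by 1.45 ± 0.19 and the sulfite oxidase Suox by 1.40 ± 0.16. Mat1a, which encodes the liver's S-adenosylmethionine synthetase, differed by 0.03 ± 0.12 at a level near the top of the scale. Bhmt differed by 0.18 ± 0.12 on a row too dim to be informative. Choline and phospholipid genes gave 2 higher and 2 lower of 16 (3 and 5 adjusted over the list alone) and no call (camera adjusted p = 0.905, adjusted p = 0.922 with an estimated correlation), with a median of 0.12 but a mean of -0.06 and a test directed downward. The choline transporter-like gene Slc44a2 rose by 1.17 ± 0.15 and Pcyt2 fell by 1.02 ± 0.13, while Pemt, which methylates phosphatidylethanolamine to phosphatidylcholine, differed by 0.18 ± 0.14. Targets of ATF4, the transcription factor of the amino acid response, rose in 9 and fell in 0 of 28 (12 and 2 adjusted over the list alone). Their median was 0.42, and the camera adjusted p was 0.000172 (adjusted p = 0.365 with an estimated correlation). Beside Asns (16.5-fold), the serine synthesis gene Psat1 rose by 2.64 ± 0.23 and Atf3 by 1.79 ± 0.18. Also on this list but outside the naming rule, Atf4, Trib3, Ddit3, Chac1, Slc7a11 and Sesn2 did not pass the threshold. The hormone gene Fgf21 rose by 1.38 ± 0.31 (limma adjusted p = 0.0436), a call lost under quantile normalization, with all rows tested, and without either normal diet array or MCD diet replicate 2. Endoplasmic reticulum chaperone genes gave 0 higher and 3 lower of 21 (4 lower adjusted over the list alone). The list had a median of -0.06 and was not called (camera adjusted p = 0.0925, adjusted p = 0.537 with an estimated correlation). It was called lower without the dimmest 50% of genes. Of these Herpud1 fell by 0.85 ± 0.13, a call lost without normal diet replicate 2 or MCD diet replicate 1. NRF2 and glutathione genes gave 4 higher and 2 lower of 26 (5 and 3 adjusted over the list alone). Their median was 0.03, without a call (camera adjusted p = 0.616, adjusted p = 0.798 with an estimated correlation).

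Genes of periportal hepatocytes fell, and those of pericentral hepatocytes went both ways. Of 22 periportal genes 12 fell and 0 rose (16 lower and 1 higher adjusted over the list alone). The median of the list was -0.86 (camera adjusted p = 1.57e-09, adjusted p = 0.235 with an estimated correlation). Hsd17b6 fell by 3.38 ± 0.33 and Etnppl by 2.24 ± 0.20. Igfals, which encodes a carrier of insulin-like growth factors, fell by 2.25 ± 0.29. Of 24 pericentral genes 4 rose and 5 fell (6 and 6 adjusted over the list alone), with a median of -0.01, a mean of -0.17, a test directed upward and no call (camera adjusted p = 0.998, adjusted p = 1 with an estimated correlation). The ammonium transporter Rhbg rose by 2.11 ± 0.28 and Cyp2c54, a member of a close family, fell by 4.25 ± 0.37. Genes of the urea cycle and amino acid catabolism fell in 10 and rose in 0 of 20 (13 adjusted over the list alone). At a median of -0.61, the list had a camera adjusted p of 2.31e-10 (adjusted p = 0.235 with an estimated correlation). The glycine decarboxylase Gldc fell by 2.05 ± 0.14, ornithine transcarbamylase, Otc, by 1.85 ± 0.12 and argininosuccinate lyase, Asl, by 1.61 ± 0.14. Other lists hold 9 of the periportal, 6 of the pericentral and 7 of the urea cycle genes. Gluconeogenesis and glycogen genes gave 0 higher and 2 lower of 14 (1 and 4 adjusted over the list alone), with a median of -0.28 and no call (camera adjusted p = 0.114, adjusted p = 0.378 with an estimated correlation). The glycogen phosphorylase Pygl fell by 1.37 ± 0.16. General hepatocyte markers, 10 of whose 15 measured members are on other lists too, fell in 2 and rose in 0, also adjusted over the list alone, with a median of -0.15 and a camera adjusted p of 0.0475 (adjusted p = 0.372 with an estimated correlation). Their call was lost under quantile normalization, with a replicate block, and without either normal diet array or MCD diet replicate 2.

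Bile acid, drug-metabolising and complement genes fell. Of 16 bile acid synthesis genes 6 fell and 1 rose (10 and 1 adjusted over the list alone). Their median was -0.67, and the camera adjusted p was 6.21e-05 (adjusted p = 0.288 with an estimated correlation). Beside Cyp7b1, the bile acid-CoA synthetase Slc27a5 fell by 2.05 ± 0.12 and the sterol hydroxylase Cyp27a1 by 1.46 ± 0.13, while Cyp7a1, the rate-limiting enzyme of the classic pathway, differed by -0.07 ± 0.49. Bile acid transport and nuclear receptor genes fell in 4 and rose in 1 of 17 (6 and 2 adjusted over the list alone). The median of the list was -0.37 (camera adjusted p = 0.0382, adjusted p = 0.387 with an estimated correlation). That call was lost under quantile normalization, median centring and without normal diet replicate 1. Within it Slco1a1 fell and the export pump Abcc4 rose by 3.90 ± 0.20. Of 23 drug-metabolising enzymes and receptors 12 fell and 0 rose (14 adjusted over the list alone). At a median of -0.85, the list had a camera adjusted p of 1.46e-07 (adjusted p = 0.372 with an estimated correlation). The carboxylesterases Ces3b and Ces2a fell by 6.87 ± 0.34 and 4.73 ± 0.24, with the caution that both have close copies. Complement and coagulation genes fell in 12 and rose in 0 of 25 (14 lower and 1 higher adjusted over the list alone), with a median of -0.57 and a camera adjusted p of 1.72e-08 (adjusted p = 0.25 with an estimated correlation). C8b fell by 1.83 ± 0.23 beside Mbl2 and C6. Acute phase and plasma protein genes instead rose in 5 and fell in 2 of 22 (7 and 3 adjusted over the list alone). Their median was 0.17, and the camera adjusted p was 0.00992 (adjusted p = 0.373 with an estimated correlation), a call lost without the dimmest 50% of genes. Lcn2 and the pentraxin Apcs (3.65 ± 0.15) rose. The serum amyloid genes Saa2 and, outside the naming rule, Saa4 fell by 1.86 ± 0.32 and 1.10 ± 0.15, both uncertain since they have close copies. Also outside the rule, Crp, Hp, Fga, Fgb and Fgg did not pass the threshold. The shared members number 3 for bile acid synthesis, 4 for bile acid transport, 6 for drug metabolism, 3 for complement and 6 for the acute phase.

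**Figure D2:**
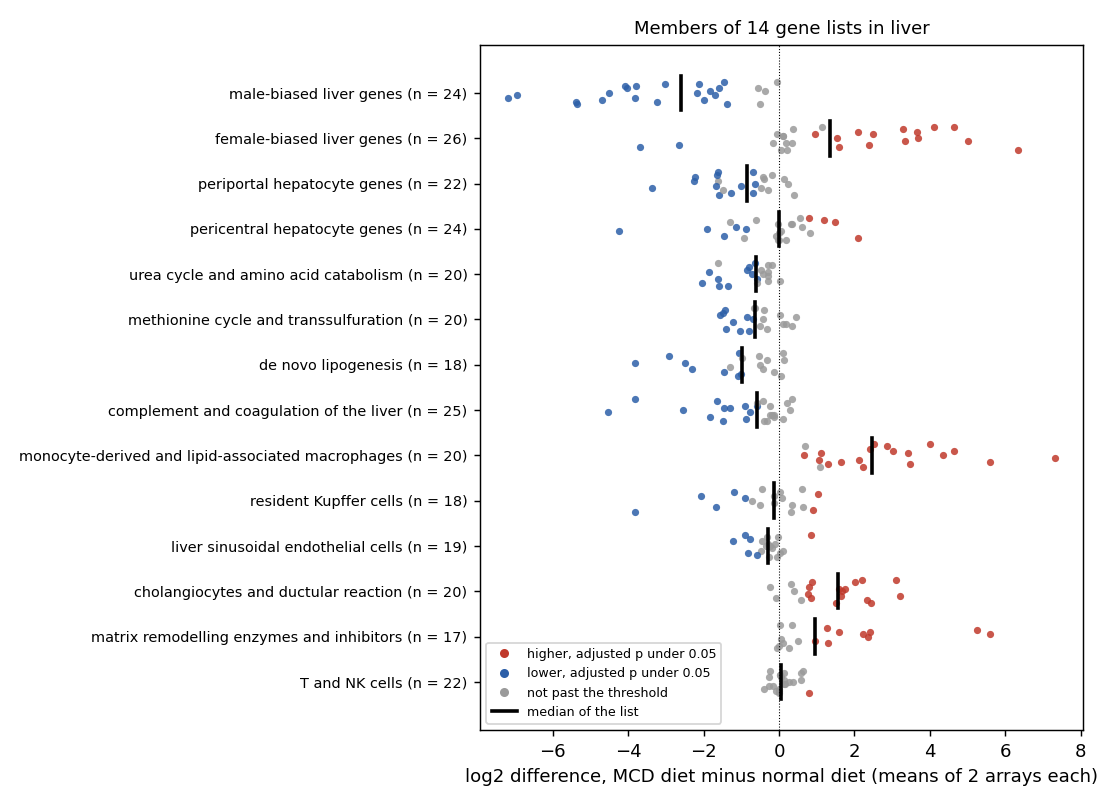
Log2 difference of MCD diet minus normal diet (horizontal axis) for each measured member of 14 of the 52 gene lists; points are genes, coloured by whether they rose, fell or did not pass an adjusted p of 0.05 in limma, and black bars are list medians. The medians run from -2.61 for male-biased genes to 2.47 for monocyte-derived and lipid-associated macrophages.

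The list of oxidative phosphorylation genes was called lower, with a median of -0.38, a camera adjusted p of 2.88e-06 (adjusted p = 0.372 with an estimated correlation), 2 lower and 0 higher of 24, also adjusted over the list alone. Sinusoidal endothelial markers fell in 5 and rose in 1 of 19 (6 and 1 adjusted over the list alone). The median of the list was -0.30 (camera adjusted p = 0.00133, adjusted p = 0.303 with an estimated correlation). Oit3 fell by 1.22 ± 0.13. Markers of other vascular endothelium rose in 2 and fell in 0 of 16, also adjusted over the list alone. The list had a median of 0.00 and was not called (camera adjusted p = 0.289, adjusted p = 0.483 with an estimated correlation). The progenitor marker Cd34 rose by 1.56 ± 0.14. Circadian clock genes gave 1 higher and 2 lower of 16 (1 and 4 adjusted over the list alone). Their median was -0.31, without a call (camera adjusted p = 0.196, adjusted p = 0.467 with an estimated correlation). Nfil3 fell by 1.22 ± 0.15. Iron and heme genes gave 2 higher and 1 lower of 15 (4 and 1 adjusted over the list alone), with a median of 0.21 and no call (camera adjusted p = 0.196, adjusted p = 0.422 with an estimated correlation).

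Markers of tissues next to the liver or carried with it were mostly flat. Mesothelial markers, of which Gpm6a rose by 2.23 ± 0.15, were called higher with a median of 0.28, 2 higher and 0 lower of 10 (4 higher adjusted over the list alone; camera adjusted p = 0.0475, adjusted p = 0.467 with an estimated correlation). The call was lost without normal diet replicate 1 or MCD diet replicate 1. The other member that rose was Krt19, also a biliary marker here, and other lists hold 3 of the 10. Adipocyte markers gave 1 higher and 1 lower of 11 (2 and 3 adjusted over the list alone). The list had a median of -0.20 and was not called (camera adjusted p = 0.434, adjusted p = 0.592 with an estimated correlation). Fabp4 rose by 1.63 ± 0.15. Erythroid and blood markers gave 1 higher and 0 lower of 9, also adjusted over the list alone. Their median was 0.04, without a call (camera adjusted p = 0.905, adjusted p = 0.922 with an estimated correlation). Of 15 pancreatic acinar, 15 skeletal muscle and 16 kidney and intestine markers 0 passed the threshold, over all genes or adjusted over the list alone. Their medians were -0.07 (camera adjusted p = 0.569, adjusted p = 0.669 with an estimated correlation), -0.12 (camera adjusted p = 0.196, adjusted p = 0.604 with an estimated correlation) and 0.02 (camera adjusted p = 0.998, adjusted p = 1 with an estimated correlation). The kidney and intestine list had a positive median and mean and a test directed downward. The largest differences in these 3 lists were -0.42 for Try4, -0.55 for Ckm and 1.16 for Vil1. Ckm passed the threshold under quantile normalization and median centring, and Vil1 under quantile normalization, without the dimmest 25% of genes, with an intensity trend and without MCD diet replicate 1. Above the median signal in normal diet livers lay 3 of the mesothelial, 7 of the adipocyte, 1 of the erythroid, 3 of the acinar, 2 of the muscle, 3 of the kidney and intestine, 18 of the sinusoidal and 8 of the other endothelial markers.

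Of the 52 lists, 30 were called with camera at a preset correlation between genes of 0.01, 17 of them higher and 13 lower. With the correlation estimated from 2 residual degrees of freedom, camera called 0 of them, the lowest adjusted p being 0.235, while 10 lists had an unadjusted p under 0.05. The rotation test fry, which asks whether the genes of a list move one way without comparing them with other genes, called 27 lists, 23 of the 30 among them. The lists that fry called and camera did not were Kupffer cells and VLDL assembly (lower), and chemokines and other vascular endothelium (higher).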

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

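The rows of the array that the comparison of genes does not use also carried differences between the diets, and this signal outside the tested genes is what marked them for a closer look. Among the 1814 rows that name several genes, 136 passed the threshold in a limma fit of all rows, 103 higher and 33 lower in MCD diet livers (7.5% of these rows, against 8.01% of the rows naming 1 gene). Among the 9137 rows with no gene name here, 234 passed, 123 higher and 111 lower (2.56%), with log2 differences from -4.83 to 6.09. No explanation was tested for either set of rows.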

How the results depend on the processing

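The alternatives were set before the data were examined, except the tests of one list within another. With quantile normalization 2349 genes changed (1303 higher, 1046 lower; 55.5% higher against 63.8% in the deposited scaling), with median centring 2189 (1181 higher, 1008 lower; 54.0%), and of the 2214 genes 1942 and 1983 kept call and direction. Leaving out dim genes, an intensity trend, all rows and the mean of a gene's rows gave 2178 to 2316. An unadjusted p under 0.05 with at least 2-fold change gave 1155 (780 higher, 375 lower), fewer by construction since smaller changes are left out. The sample numbers are shared by the diets but the labels do not say that they pair the samples; deviations of the same-numbered samples from their group means correlated at 0.0537 across genes, and the replicate block gave 1950 genes (1288 higher, 662 lower). Leaving out each array in turn gave 1050 to 1493 changed genes, 688 to 1011 higher and 362 to 482 lower, with fewer arrays and a lone array assumed to vary like those of the other diet. Between arrays of the same diet, the SD of the difference was 0.270 (normal diet) and 0.265 (MCD diet) after quantile normalization and 0.304 and 0.308 without the dimmest 50% of genes; the cause was not tested. Camera with an estimated correlation called 0 of the 52 lists (10 at an unadjusted p under 0.05), where fry called 27; estimated from 2 residual degrees of freedom, that correlation is itself imprecise. Of the 30 called lists 20 kept their call under the scalings, the filter and the block, and the same 20 without each array in turn. The neutrophil and mesothelial lists are not among them, since the filter left these 2 with too few members to test. The cholesterol synthesis and uptake list reversed, from a median of -0.41 to 0.27 (camera adjusted p = 0.259) without normal diet replicate 1, and ranged from -0.9997 to 0.2693 over the arrays left out; the cause was not tested. Of 174 genes that the naming rule allows 161 were called; 122 kept call and direction in every alternative with all arrays, the fold minimum included, and 108 also without each array in turn. How far signal over background limits the dim genes was not analysed here.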

Other observations

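The families by symbol, the comparisons of one list with another and the tests below were chosen after the main result was seen. The tests of Y-linked genes, of Socs2 and Cish and of further Kupffer cell genes had their outcomes set down before those genes were looked at. Comparisons of one list with another use the same values as the list medians, so they are not evidence independent of those medians. Annexins, proteins that bind membranes in the presence of calcium, rose in 7 of 11 members and fell in 0 (median 1.37, camera adjusted p = 0.000238 over 251 families of at least 10 members, adjusted p = 0.927 with an estimated correlation). Anxa1 rose by 3.51 ± 0.18, Anxa2 by 2.94 ± 0.22 and Anxa5 by 1.37 ± 0.14 on the log2 scale. The family was also called under quantile normalization and median centring, with 7 higher members in each and 0 and 1 lower. Integrin alpha chains with numbered symbols rose in 6 of 11 (median 0.56, camera adjusted p = 0.00745, adjusted p = 0.927 with an estimated correlation), led by Itga8 (2.42 ± 0.17) and Itga6 (1.84 ± 0.14), and 5 rose under both scalings. Toll-like receptors rose in 6 and fell in 1 of 12 (median 0.58, camera adjusted p = 0.0303, adjusted p = 0.927 with an estimated correlation). Tlr13 and Tlr8 rose by 2.36 ± 0.47 and 2.02 ± 0.30 while Tlr5 fell by 1.04 ± 0.22. The call ended under quantile normalization (adjusted p = 0.0621) and not under median centring (adjusted p = 0.0203).

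Immunoglobulin kappa variable genes rose in 4 of 13 and fell in 0 (median 0.77, camera adjusted p = 0.000817, adjusted p = 0.927 with an estimated correlation), although the list of B cell and plasma cell markers was not called. These genes have near-identical copies, so which of them changed is uncertain. Carboxylesterases fell in 8 and rose in 2 of 18 (median -0.38, camera adjusted p = 0.00495, adjusted p = 0.927 with an estimated correlation). Hydroxysteroid dehydrogenases fell in 5 and rose in 0 of 19 (median -0.20, camera adjusted p = 0.000817, adjusted p = 0.927 with an estimated correlation). Large-subunit ribosomal protein genes were higher by a small amount, 5 higher and 0 lower of 39 (median 0.29, camera adjusted p = 0.00745, adjusted p = 0.927 with an estimated correlation), but these counts depend on the scaling, with 10 higher and 1 lower under quantile normalization (median 0.18) and 3 higher and 0 lower under median centring (median 0.23). In all 15 of the 251 families were called, of which 6 kept call and direction under quantile normalization and 13 under median centring. With an estimated correlation camera called 0, and 1 had an unadjusted p under 0.05.

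The fall of male-biased and rise of female-biased liver genes was weighed against mislabelled sex, a smaller share of hepatocyte RNA and signal shared by family copies. Eif2s3y, Kdm5d and Uty had a median difference of -0.114 at levels of 4.92 to 7.02 in normal diet livers, and Xist differed by 0.07 near the floor, which argues against female mice. The female-biased genes on no other list had a median of 1.34, with 12 higher and 1 lower of 22, and fewer hepatocytes would have lowered them. Of all 26 female-biased genes 14 lay above the median signal in normal diet livers, and the others could hardly have fallen. The rises argue against a smaller hepatocyte share as the whole cause. A part for it in the fall of the male-biased genes stays open. The 9 male-biased genes outside multigene families had a median of -1.83 with 7 lower, so copies are not the whole of it. For this test alone Slco1a1 was counted as a family member and left out. Of the genes kept, C6, C8a, C8b and Cyp7b1 are also on the complement or bile acid synthesis lists. A change in growth hormone signalling, which sets these genes, may lie behind the pattern as a hypothesis. Its targets Socs2 (0.68 ± 0.20, limma adjusted p = 0.0968) and Cish (-0.51 ± 0.17, limma adjusted p = 0.126) went apart. Their mean of 0.0824 lies on the side set down as speaking against weaker signalling, but within its SE of 0.13, a condition added after the values were seen, and so leaves it open.

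The rise of markers of monocyte-derived and lipid-associated macrophages (median 2.47) was weighed against a smaller share of hepatocyte RNA and more macrophages of every kind. Sinusoidal endothelial markers had a median of -0.304 and T and NK cell markers of 0.05. The macrophage list was higher when tested within each pair of lists (camera adjusted p = 2.09e-11 and 2.3e-10, adjusted p = 0.0607 and 0.0616 with an estimated correlation). Only 5 of the 22 T and NK cell markers lay above the median signal in normal diet livers, so their flat median decides little. Of the 19 sinusoidal markers 18 did, and their median argues against a change in hepatocyte share as the whole cause. Other lists outside hepatocytes rose, cholangiocytes with a median of 1.56, myofibroblasts with 0.55 and neutrophils with 0.29, so these cell types moved apart, and a part for hepatocyte share stays open. The Kupffer cell markers on no other list had a median of -0.133, and the macrophage list was higher than the Kupffer list (camera adjusted p = 1.52e-08, adjusted p = 0.0651 with an estimated correlation), which argues against more macrophages of every kind. A loss of resident Kupffer cell transcripts as a set was tested on 8 further Kupffer cell genes, which had a median of 0.258 (quartiles 0.0718 and 0.476) with 1 higher (Il18bp) and 0 lower. Of the 8, 4 lay below the median signal of all genes in normal diet livers and could hardly have fallen. The other 4 had a median of 0.329, from -0.211 (Pcolce2) to 0.835 (Dmpk), with a lower quartile of 0.011, barely above 0. Both medians lie on the side set down beforehand as speaking against the loss. Pcolce2, however, had a normal diet signal of 3.29, little above the median of 2.95. Whether the 8 genes report on Kupffer cells in whole liver was not tested either, so they do not decide on the loss. The main list of Kupffer cell markers was called lower by fry (fry adjusted p = 0.0274), though not by camera. A loss of Kupffer cell transcripts as a set stays open, as does a loss limited to some of them, among them Clec4f and Cd163. Expression of the 8 genes by other cells stays open too and was not tested. More such macrophages and a change of expression within them both stay open, untested.

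The fall of periportal hepatocyte genes (median -0.86) was weighed against a smaller share of hepatocyte RNA and against genes that the list shares with others. Pericentral genes had a median of -0.00818 with 4 higher and 5 lower, and the periportal list was lower when tested within the pair (camera adjusted p = 0.00107, adjusted p = 0.0662 with an estimated correlation). Since the pericentral genes went both ways, with quartiles of -0.882 and 0.564, they do not decide on hepatocyte share. Of the general hepatocyte markers, the 5 below a log2 signal of 11 had a median of -0.377 (SD 0.242) and a lowest value of -0.504. That lowest value is of Apoa1, which at 10.92 in normal diet livers still lay near the top of the scale. If differences are not compressed at such levels, which was not tested, a smaller share would lower them as much as the periportal genes. Only under that condition do they argue against it as the whole cause, while a part in the fall stays open. The 13 periportal genes on no other list had a median of -0.702 with 9 lower, which argues against the shared genes alone. A change of zonation under the MCD diet may be a candidate explanation and was not tested further.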
